A study of Mus musculus with 15 samples.

How the data were processed

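RNA of sorted cells was extracted, DNase-treated and amplified with an ultra-low-input kit that primes on poly(A) tails, made into libraries by transposase tagmentation and sequenced as paired-end reads of 100 bases, per the labels' protocols. Animals of both sexes were pooled, per the labels. Such a kit does not mark the strand, so reads from a gene and an overlapping antisense partner cannot be told apart, and amplification without molecular identifiers means that counting intervals and floors cover counting error only. The submitters' processing notes list cutadapt, TopHat2 2.1, Cufflinks and HTSeq with the mm10 genome, without saying which tool made which file, and the annotation, strand setting and treatment of multiply mapped reads were not given in the sources used here. Genes with near-identical copies or processed pseudogenes, such as C4b, Eno1, Hmgb2 and ribosomal protein genes, are uncertain for that reason.

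The authors deposited whole-number counts per gene symbol for the 15 libraries, with no normalization. They also deposited FPKM values (fragments scaled to transcript length and library size by the authors), in which the headers of the symbol and position columns were found exchanged, and a text table of the surface markers of each population. Columns were matched to samples through the titles in the labels. The count table held 32763 rows, of which 28 named no usable gene (27 symbols turned into dates by spreadsheet software and 1 row called unknown). These held 0.184% to 0.323% of each library's counts and were left out of library sizes and tests. Gene positions are those of the authors' FPKM table on mm10, moved from counting at 0 to counting at 1: the RefSeq start minus the deposited start was 1 for 14437 of 23552 genes matched by symbol and 0 for 739.

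Differences between groups were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr with the group, quasi-likelihood test), in a fit of all 15 libraries with 5 groups and no covariate, and p-values were adjusted by the Benjamini-Hochberg method over 16302 genes with a threshold of 0.05. The 4 comparisons, their gene and list tests, the alternatives, the naming rule and the gene lists were fixed before the data were examined. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. TMM factors ranged from 0.825 to 1.22. The depth of each library, 12466038 to 33665687 counts, puts a floor of 3 counts at 0.0893 to 0.241 CPM. No pair of replicates agreed within sampling noise: the chi-square per gene was 28.6 to 112. The most abundant gene of a library, Rn45s or Apoe, took 1.02% to 2.84% of its counts.

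Gene lists were tested with camera (limma 3.58.1) on the edgeR fit with a preset correlation of 0.01, adjusted over 26 lists in 4 comparisons (104 tests). With it 51 tests passed, and 7 passed with an estimated correlation. The 51 include the sorting genes in GCEPB+ against GCEPB- and in GCPB+ against GPB+, which check the gates. The median of a list's fold changes and the direction of its test differed in sign, without passing, for the pallial, ventral and hedgehog lists in GCEPB+ against GCEPB-, the endothelial and pallial lists in GCEPB+ against GCPB+, the PDGF and EGF list in GCPB+ against GPB+, and the astrocyte, quiescent stem cell, ventral and hedgehog lists in GPB+ against CTX. The same held for the oxidative phosphorylation list in GCEPB+ against GCEPB-. Medians and means differed in sign for the hedgehog and Notch lists in GCEPB+ against GCPB+ and for the ventral list, which passed, in GCPB+ against GPB+. Of 527 list genes, 525 were in the count table.

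The text names, for each comparison, the sorting genes, the 8 largest rises and the 8 largest falls, and up to 4 members of each list that passed. For rises and falls, a gene had to pass the adjusted p, have no overlap between the 3 libraries of each group, reach a mean of 20 CPM in the higher group and carry an established symbol. Some list members allowed by the rule were left out.

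Replicate numbers in the titles recur in each group. Same-numbered libraries deviated together from their group means in every pair for GCEPB+ against GCPB+ (correlation across genes 0.173, 0.119 and 0.177) and for GCPB+ against GPB+ (0.155, 0.116 and 0.234), so the numbers were taken as pairing these libraries, from the data and not from a label. The main tests of these comparisons stayed unpaired, and the replicate number entered only as a block in an alternative. No pairing was taken for GCEPB+ against GCEPB-, where the libraries numbered 1 gave -0.00664, or for GPB+ against CTX. In GPB+ against CTX the same-numbered correlations were weaker but all above 0 (0.0787, 0.0556 and 0.174). There GPB+ replicate 2 with CTX replicate 1 gave 0.0708, so pairing of these libraries stays undecided. In 5 of 5 groups, replicate 2 had the highest Rn45s share. Replicate 1 had the fewest genes after libraries were thinned to the same total, also in 5 of 5. A factor shared by replicate number therefore cannot be excluded in GCEPB+ against GCEPB- or in GPB+ against CTX.

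Alternatives were other scalings (RLE and upper quartile), no filter on low counts or at least 5 CPM in 3 libraries, DESeq2 1.42.0, a fit of the 2 groups alone, the replicate number as a block, a log2 fold change above 1, limma on log2 of the authors' FPKM with pseudocounts of 1 and 0.1 (genes with an FPKM of at least 1 in 3 libraries, 14097 genes, or no filter), voom with sample weights, and leaving out each library. The tests were tried on simulated data with 200 changed genes drawn from the real means and library sizes. In the simulation of GCPB+ against GPB+ on 16044 genes, edgeR recovered 51.5% of genes changed 4-fold, 11.9% of those changed 2-fold and 0% of those changed 1.5-fold, with 3 false calls of 53. In that of GPB+ against CTX on 16003 genes it recovered 62.1%, 16.4% and 2.99%, with 1 false call of 63. On 16040 genes, it recovered 57.6%, 11.9% and 0% for GCEPB+ against GCEPB- (3 false calls of 55), and 59.1%, 13.4% and 1.49% for GCEPB+ against GCPB+ (1 false call of 57). A list raised in each simulation passed camera, and 0 of the 25 other lists did. Genes were drawn independently of each other there. The simulation therefore could not show how often camera makes false calls for lists with correlated members. The estimated correlation was 0.738 for the ribosomal list in GCEPB+ against GCPB+.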

Results

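RNA was sequenced from 5 cell populations isolated by fluorescence-activated cell sorting from brains of hGFAP::GFP mice, a reporter strain in which a human GFAP promoter marks astrocytes and neural stem cells with GFP. Of these, 4 were cells of the ventricular-subventricular zone (V-SVZ), the adult stem cell niche along the lateral ventricles, and the other, CTX, held GFP-positive astrocytes of the cortex. All V-SVZ populations were GFP-positive and negative for CD24, a surface marker of neuroblasts and ependymal cells. GPB+ cells carried PDGFRβ and lacked CD133 and EGFR. GCPB+ cells carried PDGFRβ and CD133 and lacked EGFR. GCEPB+ cells carried PDGFRβ, CD133 and EGFR, and GCEPB- cells carried CD133 and EGFR and lacked PDGFRβ. CD133, the product of Prom1, is used to enrich ventricle-contacting stem cells, and EGFR marks activated stem cells and their transit-amplifying progeny. Each population had 3 libraries, 15 in all.

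Total counts of replicates 1, 2 and 3 were 15908173, 13802947 and 24985372 in CTX, 21774170, 15879880 and 23859826 in GPB+, and 31594988, 14818000 and 33665687 in GCPB+. They were 21967337, 17301098 and 16571474 in GCEPB+, and 19081074, 12466038 and 21871223 in GCEPB-. Between 16666 and 19193 genes had at least 1 count per library, and 16302 genes were tested. Unless stated otherwise, levels below are mean CPM, counts scaled to each library's normalized total, ± SD over n = 3 libraries, and log2 fold changes are given ± SE. That SE is the absolute log2 fold change over the square root of the quasi-likelihood F statistic, not a standard error from the fit. It is unreliable for genes near the floor in a group. Within groups, the correlation of log2 CPM across genes was 0.964 to 0.967 in CTX, 0.928 to 0.955 in GPB+, 0.944 to 0.969 in GCPB+, 0.926 to 0.945 in GCEPB+ and 0.952 to 0.965 in GCEPB-. Correlations between GCPB+ and GPB+ libraries, 0.926 to 0.968, overlapped those within each of the 2 groups. The first principal component held 83.4% of the variance of the 500 most variable genes and placed GCEPB+ between the EGFR-negative groups and GCEPB-. CTX stood apart from all V-SVZ groups on the second, which held 6.61%.

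**Figure D1:**
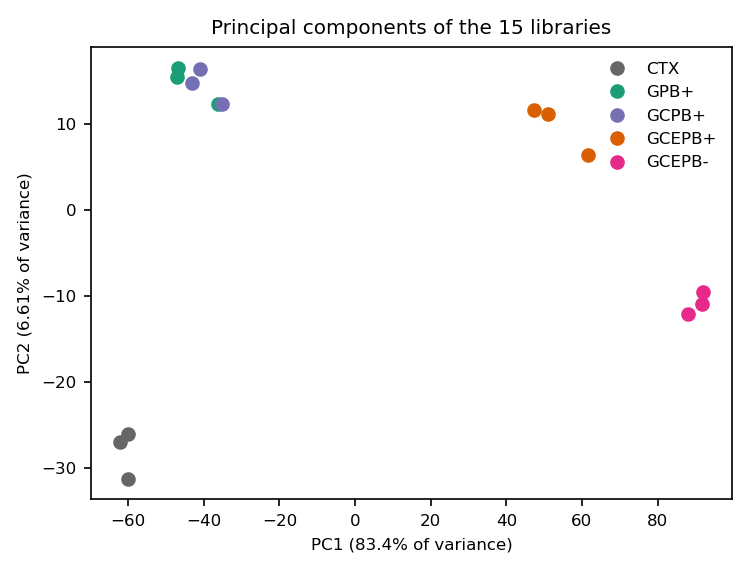
Principal component scores of the 15 libraries from log2 CPM of the 500 most variable genes; each point is a library, colored by group. On the first axis GPB+ and GCPB+ libraries lie between -47.1 and -35.1, GCEPB+ between 47.3 and 61.5 and GCEPB- between 88.1 and 92.0.

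The genes behind the sorting markers give a check of the labels, not a finding, since the cells were selected on their products or on a reporter of them. Pdgfrb (PDGFRβ; mm10 chromosome 18, 61045150 to 61085067) measured 357 ± 157 CPM in GPB+, 342 ± 65.7 in GCPB+, 45.8 ± 18.2 in GCEPB+ and 2.37 ± 1.06 in GCEPB-. Egfr (chromosome 11, 16752203 to 16913907) measured 537 in GCEPB+ (455 to 602 over its libraries) and 796 ± 48.2 in GCEPB-, against 171 ± 25.6 in GPB+ and 155 ± 52.4 in GCPB+. Prom1 (chromosome 5, 43993622 to 44102032) measured 153 ± 24.6 in GCPB+ and 28.4 ± 5.47 in the CD133-negative GPB+. In the CD133-positive GCEPB+ it measured 66.7 ± 25.1, lower than in GCPB+ (log2 fold change -1.20 ± 0.29, adjusted p = 0.00351), and in GCEPB- 48.8 ± 7.33. Gfap (chromosome 11, 102887336 to 102897200) measured 11.0 ± 3.45 in GCEPB- and 188 ± 92.4 in GCEPB+, although both were sorted as GFP-positive (adjusted p = 8.9e-06). In CTX the 4 genes measured 38.7 ± 15.4 (Gfap), 56.0 ± 18.9 (Prom1), 168 ± 4.44 (Egfr) and 182 ± 53.2 (Pdgfrb). As a list, the 4 sorting genes were higher in GCEPB+ than in GCEPB- (2 rose, camera adjusted p = 0.00157, and 0.203 with an estimated correlation; 2 rose and 1 fell adjusted over the list alone). They did not pass the camera test in GCEPB+ against GCPB+ (1 rose and 2 fell) or in GPB+ against CTX (1 rose). The gene that rose there was Gfap (adjusted p = 0.0201, but 0.0984 without CTX replicate 3, 0.0693 without GPB+ replicate 2 and 0.0589 without GPB+ replicate 3).

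**Figure D2:**
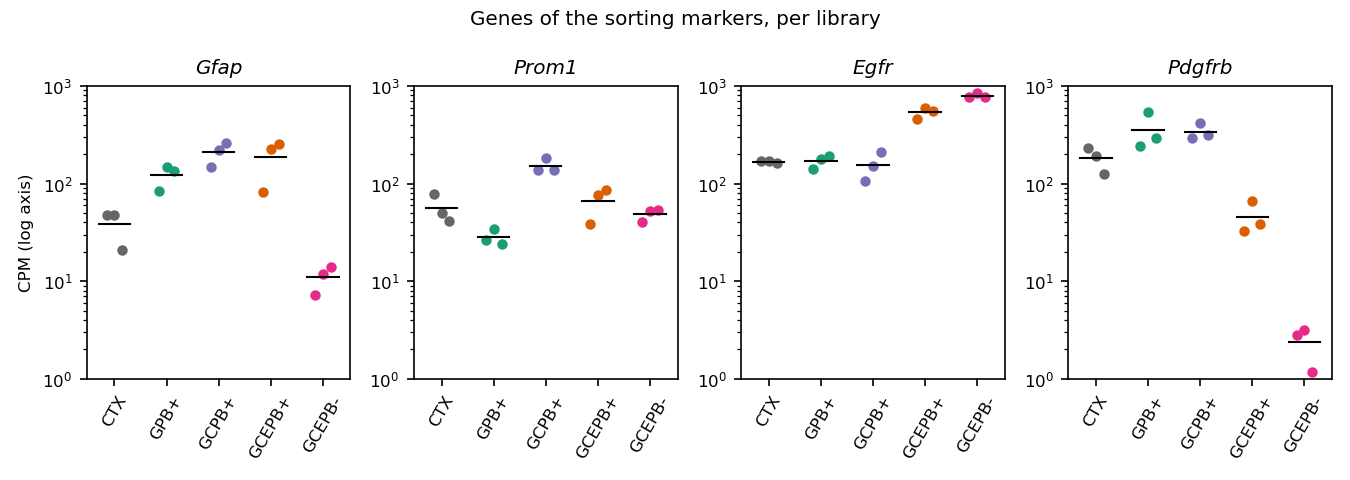
CPM of Gfap, Prom1, Egfr and Pdgfrb (log axis) in each of the 15 libraries by group; points are libraries and bars are group means. Pdgfrb averaged 45.8 CPM in GCEPB+ and 2.37 CPM in GCEPB-, and Prom1 averaged 153 CPM in GCPB+ and 28.4 CPM in GPB+.

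GCEPB+ and GCEPB- cells both carried EGFR and CD133 and differed in surface PDGFRβ, so this comparison asks which transcripts go with PDGFRβ among EGFR-positive V-SVZ cells. In GCEPB+, 24 of 28 astrocyte genes and 19 of 24 quiescent neural stem cell genes rose and none of either list fell. Among them, Clu, a secreted chaperone, measured 1891 ± 692 CPM against 82.5 ± 2.70 (log2 fold change 4.52 ± 0.27, adjusted p = 5.61e-08). Aldoc, the glial aldolase, measured 1296 ± 232 against 110 ± 25.7, a rise of 3.56 ± 0.23. In the other direction, 9 of 38 cell cycle genes and 5 of 20 genes of activated stem cells and transit-amplifying cells were lower in GCEPB+, and none was higher. The cell cycle genes that fell included Ccna2, the S- and G2-phase cyclin, at -1.48 ± 0.26, and Rrm2, which makes deoxynucleotides, at -1.33 ± 0.26.

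The largest rise in GCEPB+ was of Slc14a1, a urea transporter, at 42.4 ± 18.1 CPM against 0.490 ± 0.356 (log2 fold change 6.51 ± 0.46, adjusted p = 1.53e-07), followed by Gjb6, a connexin, at 5.42 ± 0.25. Slc14a1 lies on mm10 chromosome 18 from 78100091 to 78142119. The next were Eva1a (5.33 ± 0.44) and the zinc transporter Slc39a12 (5.25 ± 0.34). They were followed by Hhatl (4.76 ± 0.51), the complement gene C4b (4.72 ± 0.66), Naaa (4.71 ± 0.38) and Agt, the angiotensin precursor (4.62 ± 0.55). C4b has a near-identical neighbor, C4a, so its counts are uncertain. The largest falls were of the immediate early genes Ier2 (-2.57 ± 0.33, adjusted p = 4.57e-05) and Egr1 (-2.32 ± 0.54), of Trp53i11 (-2.35 ± 0.63) and of Celsr3 (-2.30 ± 0.55). Smaller falls under the same rule were of Fscn1, an actin-bundling protein (-2.24 ± 0.41), Cd24a (-2.20 ± 0.59), Mex3b (-2.14 ± 0.44) and Nsg2 (-2.13 ± 0.30). Leaving out single libraries ended the calls of Cd24a (adjusted p = 0.0918 without GCEPB+ replicate 2, 0.0754 without GCEPB+ replicate 3, 0.0991 without GCEPB- replicate 1), as DESeq2 did (0.0545). That of Celsr3 ended too (0.0501 without GCEPB+ replicate 3, 0.0554 without GCEPB- replicate 1). The call of Trp53i11 ended without GCEPB+ replicate 1 (0.0574) or 3 (0.0753) and without GCEPB- replicate 1 (0.0837) or 2 (0.0927).

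By list, the astrocyte (camera adjusted p = 6.94e-53), quiescent stem cell (1.32e-31) and cell cycle (2.09e-12) sets passed and also held with an estimated correlation between genes, at adjusted p = 0.00348, 0.000997 and 0.0332. Adjusted over the list alone, 26 astrocyte genes, 19 quiescent stem cell genes and 26 cell cycle genes passed in the direction of their set, and 1 quiescent stem cell gene passed in the other. Of 22 fatty acid oxidation genes, 12 rose in GCEPB+, with Acaa2 at 1.81 ± 0.20 (16 adjusted over the list alone; camera adjusted p = 5.24e-10, and 0.153 with an estimated correlation). Lysosomal genes rose in 10 of 19 cases, with the cathepsin Ctsl at 1.44 ± 0.19 (15 adjusted over the list alone; camera 2.87e-06, and adjusted p = 0.153 with an estimated correlation). Glycolytic genes rose in 7 of 15 cases, with Aldoa at 1.72 ± 0.17 (7 adjusted over the list alone; camera 8.21e-05, and adjusted p = 0.315 with an estimated correlation). Of 23 extracellular matrix and adhesion genes, 10 rose, among them Sparc (2.82 ± 0.22) and Tnc (2.59 ± 0.35), with 10 adjusted over the list alone (0.000226, and adjusted p = 0.153 with an estimated correlation). The activated stem cell list, in which Cdk6 fell by 1.71 on the log2 scale and Ccnd2 by 0.75 on that scale, had 10 falls adjusted over the list alone (9.13e-07, and adjusted p = 0.165 with an estimated correlation). Genes of the immediate early and dissociation stress list, or immediate early list for short, fell in 4 of 18 cases, and 1 rose. Jun fell by -1.76 ± 0.26. Adjusted over the list alone, 4 fell and 1 rose (camera adjusted p = 0.00574, and 0.153 with an estimated correlation). Effects of tissue dissociation and sorting on these genes were not tested.

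Markers of cell types outside the gate also differed between GCEPB+ and GCEPB-. Mature oligodendrocyte genes rose in 9 of 18 cases, 17 adjusted over the list alone, with Trf, transferrin, at 57.3 ± 43.9 CPM against 3.49 ± 0.811 (camera adjusted p = 7.31e-07, and 0.315 with an estimated correlation). The Trf call ended with limma on log2(FPKM + 1) without a filter (adjusted p = 0.0614). Ependymal and motile cilia genes rose in 7 of 28 cases, 8 adjusted over the list alone, with Rarres2 at 3.18 ± 0.29 (4.26e-06, and adjusted p = 0.153 with an estimated correlation). GCEPB+ replicate 1 differed from replicates 2 and 3 in these lists. Its median log2 difference from the members' means over all libraries was -1.39, against 1.65 and 1.21, for mature oligodendrocyte genes, 0.05, against 1.65 and 1.89, for ependymal genes, and -1.42, against 3.16 and 1.53, for endothelial genes. Neuroblast genes fell in 2 of 21 cases, Dlx1 and Cd24a, with 6 adjusted over the list alone (0.000597, and adjusted p = 0.247 with an estimated correlation). GCEPB- replicate 1 lay above GCEPB- replicates 2 and 3 by the same measure for neuroblast (3.33 against 0.96 and 1.39) and microglia genes (2.07 against -1.14 and -1.14), as it did for endothelial genes. GCEPB+ replicate 3, at 1.72 for neuroblast genes, lay above GCEPB- replicates 2 and 3. The Dlx1 call ended without GCEPB+ replicate 2 (adjusted p = 0.051) or GCEPB- replicate 1 (0.0609). The microglia list (3 of 13 rose, camera adjusted p = 0.0391), the BMP and TGF-beta list (4 of 18 rose, 0.0466) and the ribosomal list (0 of 26 rose or fell, lower as a set, 0.0194) passed narrowly. Adjusted over the list alone, 3, 4 and 0 genes of them passed. Their adjusted p-values with an estimated correlation were 0.516, 0.315 and 0.703. Without GCEPB- replicate 3 they were 0.215, 0.138 and 0.143, and without GCEPB+ replicate 2 they were 0.0519, 0.0519 and 0.23. Without GCEPB+ replicate 3 the microglia and ribosomal lists were at 0.246 and 0.145, and without GCEPB- replicate 2 the microglia list was at 0.234. The oligodendrocyte progenitor (1 of 18 fell), pericyte (2 of 10 rose), endothelial (2 of 17 rose) and mature neuron (1 of 13 rose) lists did not pass the camera test. Nor did the pallial (1 rose and 1 fell of 12), ventral (0 of 14), hedgehog (1 of 11 rose), Notch (2 of 14 rose), PDGF and EGF (2 of 18 rose) and oxidative phosphorylation (0 of 24) lists. The pericyte list passed without GCEPB- replicate 1 (adjusted p = 0.0114) and with a filter of 5 CPM (0.00788), and the endothelial list without GCEPB- replicate 1 (0.00486) or GCEPB+ replicate 1 (0.0073) and with that filter (0.00151).

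In total, 1513 genes were higher and 301 lower in GCEPB+ than in GCEPB- by edgeR's quasi-likelihood test at an adjusted p under 0.05, 1174 and 135 of them by more than 2-fold. The authors' FPKM values, tested with limma on log2(FPKM + 1), gave another split, 1436 higher and 704 lower, and voom with sample weights gave 1626 and 1019. With a pseudocount of 0.1 the FPKM values gave 1526 higher and 349 lower, near the main split. The count of lower genes was 562 with DESeq2, 528 with the replicate number as a block and 499 in a fit of the 2 groups alone. The count of lower genes fell to between 120 and 185 without GCEPB+ replicate 2 or 3 or any GCEPB- replicate, the fewest without GCEPB- replicate 1.

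**Figure D3:**
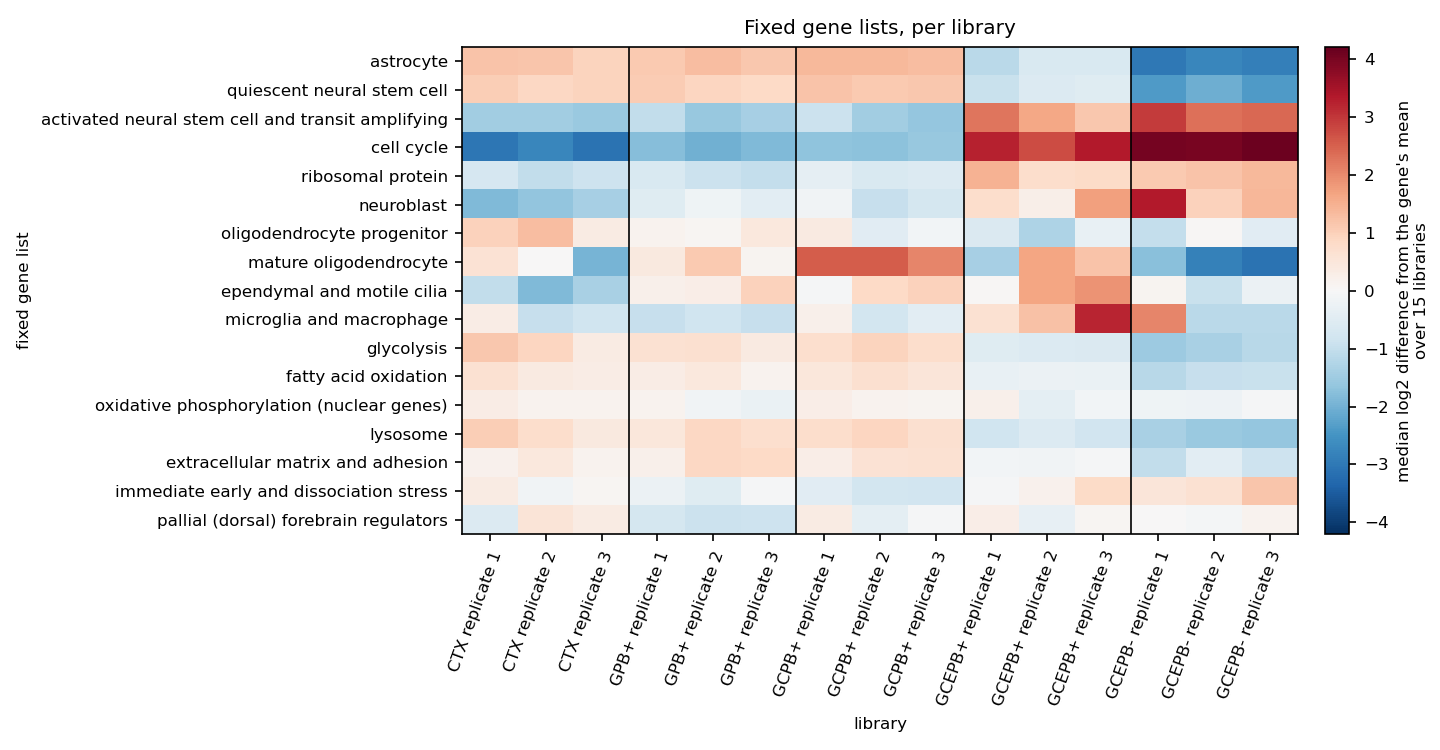
Median log2 difference of each fixed gene list's members from their own means over all 15 libraries, per library (columns, grouped by population) and list (rows); red is above and blue below the mean. The cell cycle list lies between -3.12 and -2.73 in CTX and between 3.97 and 4.12 in GCEPB-.

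GCEPB+ and GCPB+ cells both carried PDGFRβ and CD133 and differed in EGFR, so this comparison asks what goes with surface EGFR among PDGFRβ-positive cells. Cell cycle genes rose in 37 of 38 cases in GCEPB+ and none fell. Mcm6, part of the replicative helicase, measured 313 ± 87.6 CPM against 11.0 ± 0.894 (log2 fold change 4.82 ± 0.27, adjusted p = 9.24e-09), and Rrm2 measured 290 ± 74.5 against 6.29 ± 1.47. Activated stem cell and transit-amplifying genes rose in 19 of 20 cases. Among them was Cdk6, a kinase of the G1 phase, at a log2 fold change of 6.03 ± 0.25. All 28 astrocyte genes and 19 of 24 quiescent stem cell genes fell, including Gpr37l1 from 6924 ± 789 CPM in GCPB+ to 688 ± 149 in GCEPB+ and S1pr1, a sphingosine-1-phosphate receptor, from 4671 ± 401 to 975 ± 141. All 26 ribosomal protein genes rose, with Rplp0 at 2.23 ± 0.18 and Rpl3 at 1.52 ± 0.16, and all 26 also rose with RLE and upper quartile factors and in FPKM.

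The largest rise was of Cep55, which acts in abscission and was near the floor in GCPB+ (28.4 ± 9.18 against 0.0904 ± 0.157 CPM, log2 fold change 7.91 ± 0.89, adjusted p = 3.43e-06). Cep55 lies on mm10 chromosome 19 from 38055025 to 38074425. It was followed by the kinetochore gene Ndc80 (7.50 ± 0.69), Esco2 (7.49 ± 0.59), Ube2t (7.45 ± 0.79) and the transcription factor Helt (7.37 ± 0.49). Next were Trip13 (7.23 ± 0.76), Exo1 (7.21 ± 0.68) and the Notch ligand Dll4 (7.20 ± 0.83). The largest falls were of Kirrel2 (92.2 ± 23.1 CPM in GCPB+ against 3.56 ± 1.85, -4.71 ± 0.50), Kcnc4, a potassium channel (-4.57 ± 0.52), Tox2 (-4.49 ± 0.56), and Gdf10 (-4.44 ± 0.40). Next were the chemokine Cxcl14 (-4.40 ± 0.37), Prss50 (-4.19 ± 0.66), Ppp1r1b (-4.15 ± 0.46) and Ficd (-4.13 ± 0.38).

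The cell cycle (camera adjusted p = 1.04e-57), astrocyte (1.19e-31), activated stem cell (4.72e-23) and quiescent stem cell (1.18e-16) sets held with an estimated correlation, at adjusted p = 0.000997, 0.00629, 0.0336 and 0.00348. Adjusted over the list alone, 38, 28, 19 and 20 genes passed in the direction of those sets, and 1 quiescent stem cell gene passed in the other. The ribosomal set (26 adjusted over the list alone; camera 5.05e-19) had an adjusted p of 0.165 with an estimated correlation. All 19 lysosomal genes fell, among them Tpp1 (-2.06 ± 0.19) and Ctsd (-1.73 ± 0.17), with 19 adjusted over the list alone (2.95e-11, and adjusted p = 0.0673 with an estimated correlation). Glycolytic genes fell in 12 of 15 cases, with the phosphofructokinase Pfkp at -3.29 ± 0.26, and 1 rose (14 and 1 adjusted over the list alone; camera 3.08e-09, and adjusted p = 0.153 with an estimated correlation). Fatty acid oxidation genes fell in 15 of 22 cases, with Acsbg1 at -2.25 ± 0.23, and 1 rose (18 and 1 adjusted over the list alone; camera 4.26e-06, and adjusted p = 0.315 with an estimated correlation). Oxidative phosphorylation genes fell in 7 of 24 cases (7 adjusted over the list alone; camera 0.0223, adjusted p = 0.605 with an estimated correlation, and 0.115 without GCEPB+ replicate 2), and their median of -0.22 turned to 0.05 in FPKM. Extracellular matrix genes fell in 9 of 23 cases, with Bcan, the proteoglycan brevican, at -3.75 ± 0.29, and 5 rose (11 and 6 adjusted over the list alone; camera 0.0239, and adjusted p = 0.328 with an estimated correlation).

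Markers of other cell types moved here too. Neuroblast genes rose in 9 of 21 cases, with Sox11 at 265 ± 85.5 CPM against 15.1 ± 6.63 (9 adjusted over the list alone; camera adjusted p = 0.0082, and 0.321 with an estimated correlation). Mature oligodendrocyte genes fell in 5 of 18 cases, with Cnp at 265 ± 87.5 against 679 ± 118 (4 adjusted over the list alone; camera 0.0192, adjusted p = 0.605 with an estimated correlation, and 0.118 without GCEPB+ replicate 1). Pericyte genes fell in 4 of 10 cases, with Ednra at -2.25 ± 0.45 (5 adjusted over the list alone; camera 0.0466, adjusted p = 0.165 with an estimated correlation). That call ended at 0.0743 without GCEPB+ replicate 1, 0.059 without GCPB+ replicate 1 and 0.0591 without GCPB+ replicate 3. In the BMP and TGF-beta list 6 of 18 genes fell, among them Bmp6 (-3.38 ± 0.47) and Tgfb2 (-2.71 ± 0.29), and 2 rose (6 and 2 adjusted over the list alone; camera 0.0466, and adjusted p = 0.315 with an estimated correlation). The BMP list call ended with the replicate number as a block (adjusted p = 0.0955), without GCPB+ replicate 1 (0.0618) and without GCEPB+ replicate 2 (0.0503). The ependymal (4 rose and 4 fell of 28), oligodendrocyte progenitor (1 and 2 of 18), endothelial (0 and 2 of 17), microglia (3 and 1 of 13) and mature neuron (4 and 2 of 13) lists did not pass the camera test. Nor did the pallial (3 and 2 of 12), ventral (2 and 0 of 14), hedgehog (1 and 1 of 11), Notch (4 and 5 of 14), PDGF and EGF (4 and 9 of 18) and immediate early (4 and 2 of 18) lists.

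In total, 2956 genes were higher and 2933 lower in GCEPB+ than in GCPB+ (edgeR, adjusted p under 0.05), 2113 and 2207 of them by more than 2-fold. The median over all genes, to which changes are relative, was 0.11 with TMM and 0.27 in FPKM on the log2 scale, and the FPKM test called 4542 genes higher and 2319 lower.

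GCPB+ and GPB+ cells both carried PDGFRβ and differed in CD133, so this comparison asks which transcripts go with CD133 among PDGFRβ-positive, EGFR-negative cells. Prom1, the gene of the sorted marker, was 5.39-fold higher in GCPB+ (log2 fold change 2.43 ± 0.30, adjusted p = 0.00611). Beyond it, Tagln3, a calponin-family gene, measured 169 ± 16.2 CPM in GCPB+ and 84.6 ± 9.59 in GPB+ (0.99 ± 0.15, adjusted p = 0.0371; mm10 chromosome 16, 45711230 to 45724531). The remaining 3 calls lie outside the naming rule and were chosen after their values were seen. Plxna2, a semaphorin co-receptor, measured 6.61 ± 0.469 against 2.13 ± 0.314 CPM (1.63 ± 0.26, adjusted p = 0.0387). Bid, a pro-apoptotic BCL-2 family gene, had 102 counts in GCPB+ and 0 in GPB+, which makes it at least 27.9-fold higher against a floor of 3 counts over the group (adjusted p = 0.0371). Pdgfra, a marker of oligodendrocyte progenitors, was lower in GCPB+, with 2 counts over the group against 567 in GPB+ (345-fold, counting interval 95.2 to 2859, adjusted p = 0.0381). Its GPB+ level was 9.28 ± 7.40 CPM.

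Among the fixed lists, mature oligodendrocyte genes had the largest median log2 fold change, 1.62, whereas the mean was larger for the microglia list (2.37 against 1.61). All 18 oligodendrocyte genes were above 0, but none passed alone, over all genes or adjusted over the list alone (camera adjusted p = 1.06e-08, and 0.231 with an estimated correlation). The pallial regulator list was higher in GCPB+ (0.000617, and adjusted p = 0.0789 with an estimated correlation), with 4 of 12 genes passing adjusted over the list alone and none over all genes. The cell cycle (2 of 38 adjusted over the list alone; camera 0.000331), ribosomal (0 of 26; 2.05e-07), oxidative phosphorylation (0 of 24; 1.61e-05) and sorting gene (Prom1; 0.000611) lists were higher as sets. With an estimated correlation they were at adjusted p = 0.204, 0.424, 0.354 and 0.153. The sorting gene list holds the gene of the gated marker, so its result is a check of the gate, not a finding. The glycolysis (0.000199), fatty acid oxidation (0.00144), quiescent stem cell (0.0151), microglia (0.0194) and astrocyte (0.0466) lists were higher and the ventral list (0.0416) lower. With an estimated correlation their adjusted p-values were 0.315, 0.467, 0.315, 0.485, 0.605 and 0.153, and without GPB+ replicate 3 they were 0.0799, 0.16, 0.224, 0.0573, 0.419 and 0.0577. Without GCPB+ replicate 1 the quiescent stem cell, microglia, astrocyte and ventral lists were at 0.0915, 0.0806, 0.125 and 0.272, and without GCPB+ replicate 2 the fatty acid oxidation, astrocyte and ventral lists were at 0.0753, 0.193 and 0.0525. Without GPB+ replicate 1 the microglia, astrocyte and ventral lists were at 0.0754, 0.101 and 0.101, and the microglia list was at 0.0644 without GPB+ replicate 2 and 0.0676 without GCPB+ replicate 3. Apart from Prom1 and Pdgfra, no member of any list passed over all genes (edgeR), and adjusted over the list alone 1 glycolysis gene rose and, among oligodendrocyte progenitor genes, 1 rose and 2 fell. The activated stem cell, neuroblast, oligodendrocyte progenitor, ependymal, pericyte, endothelial, mature neuron, hedgehog, Notch, BMP and TGF-beta, PDGF and EGF, extracellular matrix, lysosome and immediate early lists did not pass the camera test. Of these, the extracellular matrix list passed without GPB+ replicate 1 (adjusted p = 0.0311), the lysosome list without GPB+ replicate 2 (0.0418), and the neuroblast (0.0337) and endothelial (0.0186) lists without GCPB+ replicate 1.

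In total, edgeR called 4 genes higher and 1 lower in GCPB+ than in GPB+, with 1160 genes at an unadjusted p under 0.05, and DESeq2 called 29 and 18. With the replicate number as a block, which pairs these libraries, 2 genes were higher (Prom1 and Tagln3) and 0 lower, and the adjusted p-values of Bid, Pdgfra and Plxna2 were 0.0531, 0.0531 and 0.0656. Leaving out any of the 6 libraries ended the calls of Tagln3 (adjusted p = 0.0778 to 0.197), Bid (0.0552 to 0.14) and Plxna2 (0.0977 to 0.262). That of Pdgfra ended without any but GPB+ replicate 1 (0.087 to 0.21), and that of Prom1 without GPB+ replicate 3 (0.0542). A fit of the 2 groups alone ended all but that of Prom1 (Tagln3 0.392, Bid 0.573, Pdgfra 0.0584, Plxna2 0.865).

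GPB+ cells and CTX astrocytes were both GFP-positive, and this comparison asks how PDGFRβ-positive V-SVZ cells differ from astrocytes of a non-neurogenic region. CTX is described here by GFP alone, whereas GPB+ cells were also selected on PDGFRβ, CD133, EGFR and CD24. Region and surface gate therefore cannot be told apart in this comparison. Thbs4, a thrombospondin of the extracellular matrix, measured 112 ± 42.4 CPM in GPB+ and 0.0698 ± 0.121 in CTX (log2 fold change 10.11 ± 0.63, adjusted p = 4.88e-08; mm10 chromosome 13, 92751586 to 92794818). Six3, a ventral forebrain transcription factor, measured 37.5 ± 11.4 against 0.185 ± 0.134, and its neighboring transcript Six3os1 rose by 8.89 ± 0.48. A floor of 3 counts was 0.120 to 0.218 CPM in the CTX libraries. The CTX level of Thbs4 lay below that range and that of Six3 within it, so the sizes of their rises are uncertain. In the other direction, Igfbp2, a binding protein of insulin-like growth factors, measured 354 ± 62.5 CPM in CTX and 0.727 ± 0.550 in GPB+ (-8.81 ± 0.54, adjusted p = 4.88e-08). Pallial regulators fell in 3 of 12 cases, with Dmrta2 at 11.3 ± 1.07 in CTX and 0.188 ± 0.164 in GPB+, and Otx1 at 65.4 ± 7.03 and 26.0 ± 9.55.

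The other large rises were of Crym, a thyroid hormone-binding protein (630 ± 20.2 against 3.76 ± 2.75 CPM, 7.41 ± 0.61), and the noncoding RNA Meg3 (553 ± 185 against 4.51 ± 3.88, 6.98 ± 0.55). They also included Mn1 (5.81 ± 0.34), Pmepa1 (5.18 ± 0.39) and C4b (4.60 ± 0.62). The other large falls were of the adhesion molecule Chl1 (-8.21 ± 1.34), Nrn1 (-7.80 ± 1.10), and Greb1 (-7.27 ± 0.68). Further falls were of Lgr6, an R-spondin receptor (-6.18 ± 1.11), the kinase Lyn (-5.99 ± 1.39), Cyp27a1 (-5.14 ± 1.24) and Cntnap2 (-5.14 ± 0.54). The call of Lyn ended without CTX replicate 1 (adjusted p = 0.055) or 3 (0.0503) or GPB+ replicate 3 (0.0681), and that of Cyp27a1 without CTX replicate 1 (0.0679), 2 (0.0558) or 3 (0.0666).

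Cell cycle genes were low in both groups and rose in 7 of 38 cases in GPB+, and 1 fell (19 and 1 adjusted over the list alone; camera adjusted p = 5.24e-10, and 0.0673 with an estimated correlation). Mcm6 measured 12.3 ± 3.12 against 1.80 ± 0.633 CPM, and Top2a, a topoisomerase, 9.39 ± 3.15 against 1.48 ± 1.10. Neuroblast genes rose in 7 of 21 cases and 1 fell (10 and 1 adjusted over the list alone; camera 1.61e-05, and adjusted p = 0.153 with an estimated correlation). Dlx2 among them had 201 counts over GPB+ and 0 over CTX, at least 60.4-fold higher (adjusted p = 0.00255, but 0.105 in log2(FPKM + 1)), and Tiam2 rose by 1.52 ± 0.30. Ependymal and motile cilia genes rose in 8 of 28 cases, 18 adjusted over the list alone (3.11e-11, and adjusted p = 0.0515 with an estimated correlation). Pltp among them measured 109 ± 18.1 against 19.0 ± 7.60 CPM, and Enkur had 151 counts over GPB+ and 0 over CTX, at least 45.3-fold higher. The pallial list (6 falls adjusted over the list alone; camera 0.000755) had an adjusted p of 0.0863 with an estimated correlation. Extracellular matrix genes rose in 5 of 23 cases, with Sparc at 541 ± 82.4 against 38.6 ± 11.6, and 1 fell (5 and 1 adjusted over the list alone; camera 0.0183, adjusted p = 0.315 with an estimated correlation, and 0.0538 without GPB+ replicate 2).

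Genes of the immediate early and dissociation stress list fell in 4 of 18 cases, with Ier2 at 2.17 ± 0.566 CPM in GPB+ and 10.1 ± 2.61 in CTX. Adjusted over the list alone, 6 fell (camera adjusted p = 0.00121, and 0.134 with an estimated correlation). Effects of tissue dissociation and sorting on these genes were not tested. Etv4 was the gene of the PDGF and EGF list that fell, at -2.12 ± 0.29, out of 18 (1 adjusted over the list alone; camera 0.0021, and adjusted p = 0.153 with an estimated correlation). Glycolytic genes fell in 4 of 15 cases, with Ldha at 194 ± 5.13 against 556 ± 61.3 CPM (5 adjusted over the list alone; camera 0.00355, adjusted p = 0.455 with an estimated correlation, 0.124 without CTX replicate 1 and 0.0954 without GPB+ replicate 3). The oxidative phosphorylation list was lower as a set with 0 of 24 genes past the test (0 adjusted over the list alone; camera 0.00446, adjusted p = 0.585 with an estimated correlation, and 0.131 without GPB+ replicate 3). The astrocyte (2 rose and 1 fell of 28), quiescent stem cell (4 and 2 of 24), activated stem cell (5 and 3 of 20), ribosomal (0 of 26), fatty acid oxidation (1 of 22 rose) and lysosome (1 of 19 fell) lists did not pass the camera test. Nor did the ventral (2 and 4 of 14), hedgehog (1 and 2 of 11), Notch (1 and 3 of 14) and BMP and TGF-beta (1 and 1 of 18) lists. The same held for the oligodendrocyte progenitor (2 of 18 fell), mature oligodendrocyte (0 of 18), pericyte (1 and 1 of 10), endothelial (1 of 17 fell), microglia (0 of 13) and mature neuron (2 of 13 rose) lists. Among these, the mature oligodendrocyte list passed without CTX replicate 1 (adjusted p = 0.0102) or 2 (0.0414) or GPB+ replicate 3 (0.0296), and the endothelial list without CTX replicate 2 (0.00801) or GPB+ replicate 2 (0.0359). The oligodendrocyte progenitor list passed without CTX replicate 3 (0.0272), and the activated stem cell list without GPB+ replicate 2 (0.0451).

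In total, 658 genes were higher and 440 lower in GPB+ than in CTX (edgeR, adjusted p under 0.05), 520 and 302 of them by more than 2-fold, whereas the FPKM test gave the reverse balance, 523 higher and 694 lower. DESeq2 gave 999 and 793, voom 842 and 762, and the replicate number as a block 854 and 614. Without CTX replicate 3 the counts were 368 and 219, and leaving out any of the 6 libraries lowered the second count to between 217 and 291.

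**Figure D4:**
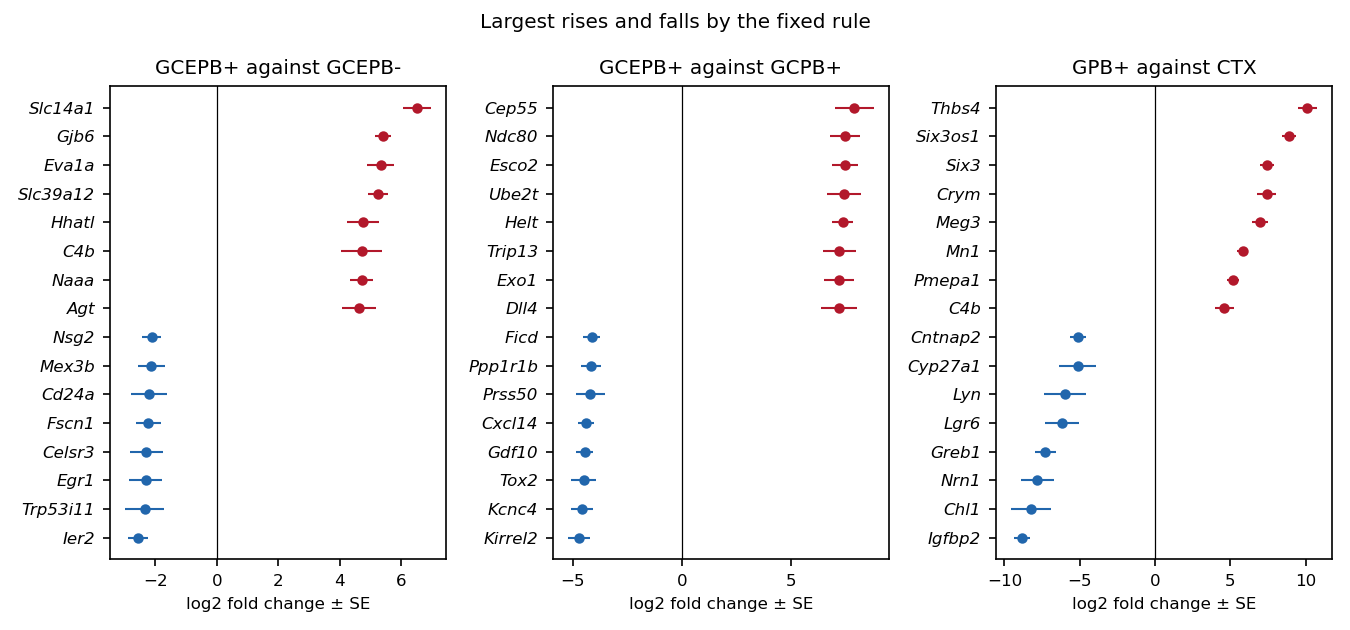
Log2 fold changes (points) ± SE (bars) of the 8 largest rises (red) and 8 largest falls (blue) named by the fixed rule in 3 comparisons; each axis is log2. Slc14a1 leads the rises of GCEPB+ against GCEPB- at 6.51, Cep55 those of GCEPB+ against GCPB+ at 7.91, and Thbs4 those of GPB+ against CTX at 10.11.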

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

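No test here was chosen after its result was seen, and the tests on the spread of linear positions and on positions by direction were added after the others had been run. Groups of 3 libraries were not tested for outlying libraries, and no contrast was made in more than 1 tissue or condition.

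Data outside the comparisons held a signal. The 27 rows whose symbols had become dates, with 1 row called unknown, held up to 0.323% of a library's counts (GCEPB+ replicate 3), well above a floor of 3 counts. In a fit that kept them, 21 were tested: 2 rose in GCEPB+ against GCEPB-, 6 rose and 5 fell in GCEPB+ against GCPB+, none passed in GCPB+ against GPB+ (edgeR; no other tool was run on them), and 1 rose and 1 fell in GPB+ against CTX. The spreadsheet dates belong to March and Sept gene symbols and do not say which gene of each family a row holds.

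GCEPB+ lay between GCPB+ and GCEPB-: over 6376 genes that differed between GCPB+ and GCEPB-, the median position of GCEPB+ was 0.680 of the log2 distance from GCPB+ (interquartile range 0.512 to 0.825). It moved by 0.00252 over TMM, RLE and upper quartile factors, which hardly differ here. With the groups shifted to the scaling of the FPKM values, the medians for genes higher and lower in GCEPB- than in GCPB+ were 0.773 and 0.558. Those shifts, 0.196 for GCPB+ and -0.0159 for GCEPB-, were small beside the log2 differences above 1 by which the genes were chosen. They could hardly have moved the position outside the range of both groups, so the test does not decide on the TMM scaling as its source. A mix of RNA from GCPB+ and GCEPB- cells, through doublets or sort impurity, may give such positions and cannot be told apart from cells of an intermediate kind here, since the bounds come from simulated mixes, and the PDGFRβ gate, which the design names, stays open as a biological source. Over 632 genes at least 8-fold higher in GCPB+ than in GCEPB-, the linear position had a median of 0.844 and an interquartile range of 0.108. That range was 0.0857 to 0.0989 in 10 simulated mixes. The mixes were set at a share of 0.714 of GCEPB- RNA, the median linear position over the 6376 genes, below the 0.844 of these genes. The spread depends on that share, so the ranges do not decide whether a mix gives these positions. Another 43 genes lay outside the range of both populations, where the simulated mixes gave at most 14. That count fell between the bounds set beforehand for and against a mix, so it does not decide either.

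GPB+ replicate 1 stood apart from GPB+ replicates 2 and 3 on the third principal component (-21.2, against -5.61 and -1.47). RNA of another cell type in it cannot be told apart from other sources: of 8 fixed lists of other cell types, the highest median difference to replicates 2 and 3 was 0.0835 on the log2 scale, but members moved both ways, which leaves that bound undecided. Of 18 mature oligodendrocyte genes 5 were higher and 6 lower by at least 1, Mobp and Mbp being higher by 3.10 and 1.65 while Cnp (524 CPM) lay between those replicates, and the endothelial list was lower by 1.11 (0 of 17 genes higher and 9 lower by at least 1) and the ependymal list by 0.55 (3 of 28 higher and 10 lower). Fewer captured genes may account for it: thinned to 12431567 counts, it held 16207 genes, the fewest of the 15 libraries, although GCPB+ replicate 1, the next at 16583, did not stand apart from its group on that component (-1.79, against -1.58 and 3.08) and replicate 1 held the fewest in 5 of 5 groups. The label gives no biological difference between replicates, so none was tested.

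The mature oligodendrocyte list was higher in GCPB+ than in GPB+ for 18 of 18 genes, with a weighted mean of 1.04. Myelin RNA from outside the sorted cells, carried at a single amount per library, may give this, but the test of it decides little. The fold changes of the members differed by no more than their errors (heterogeneity chi-square p = 0.242). Those errors were derived from the F statistic of each gene and were wide, with an SE of 0.285 for Cnp and 1.64 for Gjb1. The test also takes members as independent, whereas their estimated correlation was 0.526. The GFP gate should remove oligodendrocytes, no member is on another fixed list, and abundant members included Cnp at 568 to 803 CPM and Mbp at 132 to 177 in GCPB+. Within libraries the ratios were not uniform: GPB+ replicate 1 held 49.8 CPM of Mobp and 1.05 of Mal, and GCPB+ replicate 1 held 30.9 and 40.6. The CD133 gate stays open as a biological source.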

How the results depend on the processing

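All alternatives were planned before the data were examined. Of 3642 gene values under an alternative, 3463 kept their side of the threshold, 170 fell short of it (107 of them with a library left out), 9 newly passed and 0 reversed direction. For genes and for lists, a change of sign counted as a reversal only where the main or the alternative value passed. Where neither passed, it counted as kept. Of 1040 list values (estimated correlation, RLE, the 5 CPM filter, the block and libraries left out; lists were not tested with camera on FPKM), 929 kept their side, 94 fell short (44 of them with an estimated correlation, which lowered the count of lists past the test from 51 to 7), 17 newly passed (14 of them with a library left out) and 0 reversed direction. Calls of lists that ended with a filter of 5 CPM were the microglia (0.207) and BMP (0.0576) lists in GCEPB+ against GCEPB-, the oligodendrocyte (0.0743), pericyte (0.0801), BMP (0.0934) and oxidative phosphorylation (0.0507) lists in GCEPB+ against GCPB+, and the astrocyte (0.0907), microglia (0.61) and ventral (0.334) lists in GCPB+ against GPB+. Lists that newly passed with that filter were the endothelial (0.00151) and pericyte (0.00788) lists in GCEPB+ against GCEPB- and the oligodendrocyte progenitor list in GPB+ against CTX (0.0391). RLE and upper quartile factors moved no count by over 1.5 times. Where a count moved, the cause was not tested, except that a fold threshold lowers a count by construction.

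For genes lower in GCEPB+ than in GCEPB- (301), DESeq2 gave 562, the 2-group fit 499, voom 1019, log2(FPKM + 1) 704 and 668 without a filter, and a log2 fold change above 1 gave 135. With log2(FPKM + 0.1) the count stayed near the main one, at 349. Leaving out a library gave 120 to 406. For genes higher in GCEPB+ than in GCPB+ (2956), log2(FPKM + 1) gave 4542 and 4490 without a filter. For GCPB+ against GPB+ (4 higher and 1 lower), DESeq2 gave 29 and 18, the 2-group fit 1 higher, log2(FPKM + 1) 1 and 0, log2(FPKM + 0.1) 1 and 0, log2(FPKM + 1) without a filter 2 and 2, no filter or at least 5 CPM 2 lower, and leaving out a library 0 to 2 higher and 0 to 1 lower. In the simulation of that comparison on 32735 genes DESeq2 made 34 false calls of 112. For GPB+ against CTX (658 and 440), DESeq2 gave 999 and 793, log2(FPKM + 1) 694 lower, voom 762 lower, and leaving out a library 368 to 603 higher and 217 to 291 lower.

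With the replicate number as a block, GCPB+ against GPB+ gave 2 and 0 genes, and 3211 and 3195 in GCEPB+ against GCPB+, among which 2909 of 2956 and 2904 of 2933 genes remained. For the genes named and the lists tested in these 2 comparisons, the calls that changed are printed beside their results. GCEPB+ and GCEPB- libraries did not deviate together in every pair (correlations of -0.01, 0.07 and 0.10 between same-numbered libraries), and the block gave 1714 and 528 genes, with Egfr at an adjusted p of 0.0372 in place of 0.0943 and the microglia and BMP lists at 0.0592 and 0.093. For GPB+ and CTX libraries (correlations of 0.08, 0.06 and 0.17) it gave 854 and 614, with Prom1 at 0.0423 and Pdgfrb at 0.0381. Depth limits low genes: 3 counts correspond to 0.0893 to 0.241 CPM.

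All splits of the 6 libraries of a comparison into 3 and 3 number 10, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes: 1814 against at most 3 in another split for GCEPB+ against GCEPB-, 5889 against 0 for GCEPB+ against GCPB+, 5 against 2 for GCPB+ against GPB+, and 1098 against 0 for GPB+ against CTX.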

Other observations

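The naming of genes outside both neighbors and of genes along the series, and the library features, were chosen after their values were seen. A set of 43 genes was expressed in GCEPB+ outside the range of both GCPB+ and GCEPB-, 27 above and 16 below, by at least 1.5-fold with an adjusted p under 0.05 against each (edgeR). The 4 furthest above with at least 20 CPM were Notum, a Wnt deacylase (58.1 ± 20.6 CPM in GCEPB+, 3.64 in GCPB+ and 18.0 in GCEPB-), Vnn1 (76.7 ± 1.70, 16.7 and 25.1), Urah (25.6 ± 4.75, 8.72 and 2.28) and Lgals3, galectin-3 (71.8 ± 25.3, 18.0 and 26.6). Of those with an established symbol and at least 20 CPM in a neighbor, the 4 furthest below were Smoc1 (3.49 ± 1.28 CPM, against 25.4 and 14.1), Cdh20 (9.55 ± 0.782, against 61.6 and 33.1), the phosphatase Dusp1 (10.4 ± 1.95, against 35.1 and 45.5) and Fem1a (16.1 ± 2.94, against 57.1 and 35.3). The call of Notum against GCEPB- ended without GCEPB+ replicate 1 (adjusted p = 0.0979) or 2 (0.0803) or GCEPB- replicate 1 (0.118) or 3 (0.127). That of Fem1a ended without GCEPB+ replicate 1 (0.088) or 3 (0.104) or GCEPB- replicate 1 (0.0937) or 2 (0.117), and in log2(FPKM + 1) (0.0741). That of Dusp1 against GCPB+ ended without GCPB+ replicate 1 (0.0506) and with voom (0.0822).

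Crym, the thyroid hormone-binding protein that was higher in GPB+ than in CTX, measured 630 ± 20.2 CPM in GPB+, 182 ± 32.5 in GCPB+, 44.4 ± 20.7 in GCEPB+ and 3.42 ± 2.31 in GCEPB-, and 3.76 ± 2.75 in CTX; its difference between GCPB+ and GPB+ did not pass (edgeR adjusted p = 0.498). Of the pallial regulators, Dmrta2 measured 11.3 ± 1.07 CPM in CTX, 0.188 ± 0.164 in GPB+ and 2.05 ± 1.15 in GCPB+. Otx1 measured 65.4 ± 7.03, 26.0 ± 9.55 and 46.9 ± 5.67 in the same groups, and Nr2f1 21.2 ± 12.1, 10.7 ± 3.86 and 27.7 ± 1.49. Zic2, on the ventral and septal list, went the other way from Six3, with 14.5 ± 0.375 CPM in CTX and 0.207 ± 0.0779 in GPB+.

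Differences between lists in the position of GCEPB+ between GCPB+ and GCEPB- were not tested. The median was 0.882 of the log2 distance for 26 ribosomal protein genes and 0.832 for 38 cell cycle genes, 0.536 for 28 astrocyte genes, 0.529 for 24 quiescent stem cell genes and 0.403 for 18 mature oligodendrocyte genes. Over all genes that differed it was 0.756 for those higher and 0.591 for those lower in GCEPB- than in GCPB+. On the linear scale, for members at least 8-fold higher in GCPB+, the medians were 0.853 for 21 astrocyte genes, 0.850 for 14 quiescent stem cell genes and 0.471 for 8 mature oligodendrocyte genes.

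Library features followed the replicate number. The share of Rn45s, ribosomal RNA, was highest in replicate 2 in 5 of 5 groups (up to 2.84%), and replicate 1 held the fewest genes after thinning in 5 of 5 groups.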
